A study of Mus musculus with 4 samples.

How the data were processed

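The data were 4 RNA-seq libraries of mouse T-helper 2 primary cells, each with 1 gene table. Per the file headers, the authors counted fragments with featureCounts version 1.4.6-p4 over exons, summed by gene of GENCODE M13, with paired fragments whose ends both aligned and with strand setting 1. The alignments are named star2 in the headers, with no version. The labels give mm10 as the assembly, and the read-me texts list separate signal tracks for the plus and minus strands. The deposited values are raw counts per gene, not normalized, and the tables also give each gene's exon coordinates and summed exon length. The labels call the assay total RNA-seq, while the linked library protocol is named for poly(A) RNA. Paths in the headers name a time point of 24 hours, which the labels do not give. Groups and replicate numbers were taken from the labels.

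Before the data were examined, tests had been planned for TPM and estimated counts. The tables held counts only, so TPM was computed as count over exon length, rescaled to the same total in each library, and the counts entered the count tests unrounded and unchanged. Symbols were matched by gene ID without version for 50376 of 50600 IDs, and the 224 unmatched IDs held under 1% of the counts of each library. Exons of each gene were merged from the coordinates in the tables, and the bases shared with exons of genes on the other strand were summed. That geometry was tested on a made-up locus.

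Levels were tested against 1 TPM with limma 3.58.1, on log2(TPM + 0.1), as a moderated one-sample test with trended and robust variance, two-sided, for genes with a count in at least 1 library. Spread between replicates was tested with edgeR 4.0.16, with an intercept-only quasi-likelihood fit, TMM factors and its default expression filter, and each gene's quasi-dispersion was set against the trend, upper tail. Both used Benjamini-Hochberg adjustment and a threshold of 0.05. Contrasts between lists or genes were differences within a library, with an exact sign-flip permutation test, two-sided. Deviations of a replicate are log2 CPM with a prior of 0.5. Ratios of summed counts have exact conditional binomial intervals. DESeq2 1.42.0, R 4.3.3, Python 3.11.15 and scipy 1.17.1 were also used.

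Both genome-wide tests were tested on simulated counts drawn from these libraries, with the same dispersion for all genes. For 200 genes put at 4 TPM, the level test called 99.5% above 1 TPM, and for 197 genes at 0.25 TPM it called 95.4% below. These genes were drawn only from those of long exon length, and only genes with a simulated count were scored. The shares may therefore overstate what the test could find in short genes such as Il4.

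The 27 lists fixed in advance covered the Th2, Th1, Th17, Treg and Tfh programs, 8 T cell states, 10 other cell types and 4 library-type lists. The rule for named genes took 12 lineage factors and cytokines, up to 4 members of each list with the highest mean TPM, the 10 protein-coding genes with the highest mean TPM, and up to 10 variable genes, of which there were none. Genes outside it are marked as chosen after their values were seen, or are features opposite a list gene. Alternatives were other pseudocounts, levels, filters, scalings and tools, and each replicate left out in turn. Totals without CT010467.1, list members with no shared exon bases, other limits for the features opposite list genes, and other choices of genes for the deviation of a replicate were added after the data had been seen. Depth was 1804217 to 2711948 counts per library, and 3 counts, the limit that a count of 0 allows, were 1.11 to 1.66 CPM.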

Results

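RNA was sequenced from T-helper 2 cells, the CD4 T cell subset known for making interleukin-4, interleukin-5 and interleukin-13. The cells were primary cells of C57BL/6NJ mice. The series held 4 libraries of 1 group, biological replicates 1 to 4, with no other cell type and no control. The labels gave all 4 libraries the same donor record and did not say whether the replicates came from separate mice. The p-values therefore measure only the spread between these samples, which may be in part technical. Counts of Tsix and of genes on chromosome Y differed between the replicates, as given below, so the libraries may not all come from like animals. The tables held fragment counts for 50600 genes. Replicate 1 had 1804217 counts in 13705 genes, replicate 2 had 1846441 in 13900, replicate 3 had 2711948 in 14083 and replicate 4 had 2169955 in 12398. As a check for a library entered more than once, the chi-square per degree of freedom between libraries lay between 2.21 for replicates 1 and 2 and 13.9 for replicates 1 and 4.

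Counts lay mainly in genes whose exons share bases with a gene on the other strand. Such genes made up 8189 of the 50600 genes and 26.2% of the exon length, but held 93.8% ± 1.65 of the counts (SD, n = 4). Without CT010467.1 and mt-Nd6, the share was 92.9% ± 1.47. Actb, the cytoplasmic actin of all cells, had 276, 324, 299 and 48 counts in replicates 1 to 4. Gapdh, a glycolytic enzyme, had 121, 136, 91 and 38. Tsix, which lies opposite Xist on chromosome X, had 4004 and 3437 counts in replicates 1 and 2, where Xist had 85 and 94. mt-Nd6, the only coding gene of the mitochondrial light strand, had between 35801 and 49430 counts, and the 12 coding genes of the heavy strand together had between 4207 and 7040. In each library mt-Nd6 exceeded those 12 genes, by 6.13-fold at the least. A count is therefore given here as the count of a gene or feature on the strand the counting selected, and is not read as the expression of that gene.

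CT010467.1, a ribosomal RNA gene, Phykpl, mt-Nd6 and Gm20721 had the highest mean counts of all genes. CT010467.1 lies opposite Gm42418 and shares 1822 exon bases with it. Phykpl, which shares 809 exon bases with the RNA-binding protein gene Hnrnpab, had 51862 ± 2599 counts (SD, n = 4). Gm20721, opposite the G protein gene Gnas, had 25724 ± 1215. Tlcd1, whose largest shared part is with the ribosomal protein gene Rpl23a, had 18410 ± 815, and Mettl23, opposite the splicing factor gene Srsf2, had 12303 ± 257. By the rule fixed for named genes, which leaves out mitochondrially encoded genes, the 10 protein-coding genes highest in TPM were Gm20721, Gm17606, Phykpl, Gm26602, Mettl23, Acat3, Gm17617, Tlcd1, 1810049J17Rik and Wdr38. Each shares exon bases with a gene on the other strand. Their means ran from 2143 TPM for Wdr38 to 12433 TPM for Gm20721.

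Lineage factors and cytokines of helper cells were compared within each library, since the labels name the cells T-helper 2. Gata3, the transcription factor that directs Th2 differentiation (chromosome 2), had 20, 47, 44 and 22 counts, or 5.96 ± 2.62 TPM (SD, n = 4). Tbx21, the Th1 factor on chromosome 11, had 0 counts in each library. With Tbx21 put at 3 counts over the 4 libraries summed, the limit that a count of 0 allows, Gata3 was 27.7-fold higher per exon base. The lower 95% exact conditional limit of the ratio was 22.2. Gata3 shares 155 exon bases with Gm13256 on the other strand and Tbx21 shares none, so the ratio may not be one of expression. Bcl6, the follicular helper factor, had 2 counts in all, and the Gata3 to Bcl6 ratio of the summed counts per exon base was 112 (95% exact conditional interval 30.4 to 934). Foxp3, the regulatory T cell factor on chromosome X, had 718, 730, 706 and 601 counts, and the difference of Gata3 minus Foxp3 in log2(TPM + 0.1) was -4.44 ± 0.58, below 0 in 4 of 4 libraries. Foxp3 shares 590 exon bases with Ccdc22 and 373 with Gm36995 on the other strand. The intervals and floors of all comparisons, shares of counts included, cover counting error only.

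Il4 had 24, 21, 25 and 26 counts, or 14.0 ± 1.5 TPM. Ifng, the Th1 cytokine, had 2 counts over the 4 libraries, and the ratio of Il4 to Ifng per exon base was 50.7 (95% exact conditional interval 13.6 to 424). Il17a, the Th17 cytokine, had 1 count, with a ratio of 91.6 (16.1 to 3656). Il21, a cytokine of follicular helper cells, had 23, 26, 42 and 26 counts and shares 469 exon bases with Gm12534 on the other strand. The log2 difference of Il4 minus Il21 was 1.82 ± 0.36 (SD, n = 4), and -0.25 on CPM, which is not scaled by gene length. Il13 and Il10 had 1 count each over the 4 libraries and Il5 had 1. On so few counts the ratio of Il13 to Ifng per exon base, 0.537 (95% exact conditional interval 0.0091 to 10.3), gave no direction. The log2 differences were 5.82 ± 0.61 for Gata3 minus Tbx21 and 5.38 ± 0.52 for Gata3 minus Bcl6. They were 5.77 ± 1.59 for Il4 minus Ifng, 6.48 ± 1.43 for Il4 minus Il17a and -0.64 ± 1.33 for Il13 minus Ifng. The size of these differences rested on the pseudocount at zero counts. With each zero of the subtracted gene put at 3 counts per library, they were 2.55 ± 0.63 for Gata3 minus Tbx21, 3.86 ± 0.79 for Gata3 minus Bcl6, 3.71 ± 0.80 for Il4 minus Ifng and 3.22 ± 0.75 for Il4 minus Il17a, each above 0 in 4 of 4 libraries. The exact sign-flip permutation test, two-sided, gave p = 0.13 for each pair except Il13 minus Ifng, at p = 1.0, and 0.13 is the smallest value that 4 libraries allow.

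Whole programs were compared in the same way, through the median log2(TPM + 0.1) of each fixed list. The Th2 list stood above the Th1 and Th17 lists by 4.11 ± 1.23 each (SD, n = 4) and above the Tfh list by 1.46 ± 0.79, in 4 of 4 libraries. Against the Treg list the difference was -0.80 ± 1.02, above 0 in 1 of 4 libraries. The exact sign-flip permutation p, two-sided, was 0.13 for the first 3 comparisons, the smallest value possible, and 0.25 for the Treg list. The median of the Th1 and of the Th17 list was that of a gene with 0 counts in every library. With each such zero put at 3 counts per library, the differences were 0.74 ± 0.88 for Th1, 0.97 ± 1.42 for Th17 and 0.17 ± 0.82 for Tfh, each above 0 in 3 of 4 libraries. Among members with a mean count of at least 10, which were 10 Th2, 1 Th1, 2 Tfh and 0 Th17 genes, the Th2 minus Th1 difference was -1.47 and the Th2 minus Tfh difference -0.095. The direction of these 2 comparisons therefore rested on members with few counts, while Th2 minus Treg was -0.39. Among members that share no exon bases with the other strand, a choice made after the data had been seen, Th2 minus Th1 and Th2 minus Th17 were 2.41 each, Th2 minus Tfh 0.99 and Th2 minus Treg -2.51 ± 1.33. Without replicate 4, Th2 minus Treg was -0.40.

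Of the 21 Th2 genes, 9 were called above 1 TPM and 3 below, and 6 had 0 counts in all libraries (limma moderated test, adjusted p under 0.05). Ptgdr2, the prostaglandin D2 receptor of Th2 cells, had 54.7 ± 10.8 TPM, the highest in the list on the strand counted, and shares 1031 exon bases with Ccdc86, which had 10, 16, 7 and 8 counts. The transcription factors Irf4 and Batf, with no shared exon bases, were at 15.9 ± 8.15 and 8.61 ± 4.13 TPM. In the Th1 list 1 of 14 genes was called above, Il12rb2 at 19.7 ± 3.53 TPM, which shares 1519 exon bases with Serbp1. Runx3, Stat4 and Fasl had 1.12, 0.830 and 0.463 TPM. In the Th17 list 0 of 10 were called above and 4 below, and Ahr had 0.141 TPM. In the Treg list 5 of 10 were above, with Nrp1 at 11.02 ± 1.59 TPM, Itgae at 8.86 ± 1.93 and Tnfrsf18 at 7.27 ± 1.66. In the Tfh list 2 of 10 were above, with Btla at 14.8 ± 4.92 TPM beside Pdcd1 at 1.89 and Cxcr5 at 1.69.

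Features on the other strand gave a second set of values for genes of the fixed lists, in a comparison chosen after the data had been seen. A feature was used for a gene when it shares at least 50 exon bases with that gene and with no other gene on the other strand. The feature opposite Gata3, Gm13256, had 1364, 1638, 1747 and 2006 counts. Gm44876, opposite the interleukin-4 receptor gene Il4ra, had 870 ± 60.2 counts (SD, n = 4), and A430072P03Rik, opposite the transcription factor gene Gfi1, had 275.0 ± 38.2. Gm48719, opposite the T cell receptor complex gene Cd3e, had 2722 ± 128 counts. Bach2os, opposite Bach2, had 1878 ± 128 and Gm43352, opposite Lef1, had 841 ± 106. Gm16008, opposite the Treg gene Tnfrsf18, had 4488 ± 235. Opposite Foxp3, Ccdc22 had 5, 1, 5 and 15 counts and Gm36995 had 0, 0, 0 and 1, so that the order of Gata3 and Foxp3 in these counts was the reverse of that in their own. Gm12214 opposite Il5 had 3.50 ± 3.00 counts, Gm15655 opposite Maf 3.00 ± 0.816, Gm33460 opposite the Th1 gene Eomes 1.5 ± 0.577 and Gm12534 opposite Il21 2.00 ± 0.816. Tbx21, Ifng, Il4 and Il13 share no exon bases with the other strand and had no such value.

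**Figure D1:**
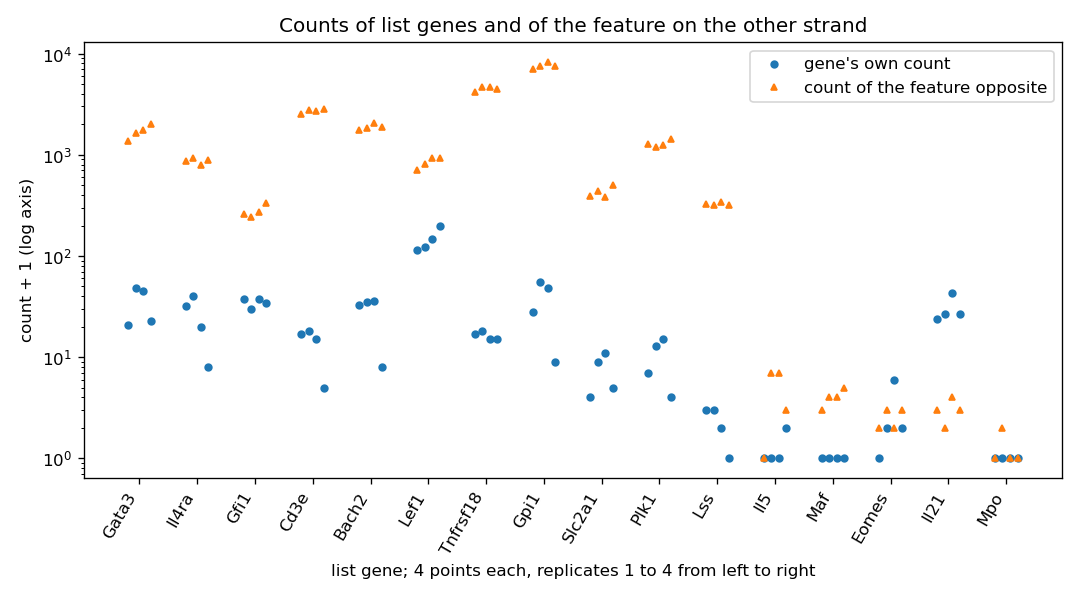
Counts per library, plus 1, on a log axis, for 16 list genes (circles) and for the feature on the other strand of each (triangles), with replicates 1 to 4 from left to right; the genes were chosen after their values were seen. The feature opposite Gata3 had 1364 to 2006 counts where Gata3 itself had 20 to 47, and the features opposite Il5, Maf, Eomes, Il21 and Mpo had 6 counts or fewer.

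Features opposite genes of metabolism and division had counts in each library. Gm26762, opposite the glycolytic enzyme gene Gpi1, had 7608 ± 462 counts and Gm12868, opposite the glucose transporter gene Slc2a1, had 429 ± 55.3. Gm44985, opposite the mitotic kinase gene Plk1, had 1287 ± 99.7. In cholesterol synthesis, 4930483K19Rik opposite Lss had 325 ± 9.91 counts. Over the lists of T cell states, 20 of 20 genes with such a feature had more than 3 counts in it in each library, over the Th2, Th1, Th17, Treg and Tfh lists 7 of 15 did, and over the lists of other cell types 0 of 4 did. The exact test of Fisher, two-sided, gave p = 9.4e-05 for state lists against other cell types. Among those 4 genes, Alas2 was scored only on Mir3620, a microRNA gene of 61 bases with 0 counts in each library. Its failure to pass therefore carries little weight. Some features were near the limit: Hmgxb3, opposite the macrophage gene Csf1r, had 7, 4, 8 and 3 counts, and Pitrm1, opposite Pfkp, had 15, 30, 16 and 4. With at least 3 counts as the limit and features opposite more than 1 gene also used, such as Apex2 opposite Alas2, 22 of 22 and 2 of 4 genes passed (exact p = 0.018). With more than 10 counts in each library as the limit, 16 of 20 and 0 of 4 genes passed (exact test of Fisher, p = 0.0066). Few counts in a feature that is itself a protein-coding gene, such as Pitrm1, may also be wrong-strand fragments of its own transcripts. The limit cannot separate these from fragments of the list gene. Only 4 genes stood for the other cell types, and genes of one list are not independent.

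State lists differed in their own counts. The pan-T list had a median log2(TPM + 0.1) of 2.41 ± 1.05 (SD, n = 4), with 11 of 16 genes called above 1 TPM. Cd247, the zeta chain of the T cell receptor complex, had 159 ± 21.7 TPM and shares 3007 exon bases with Pou2f1, while Trac, Trbc2 and Trbc1, the receptor constant regions, had 15.2, 13.7 and 13.1 TPM. The cell cycle list was at 2.38 ± 1.24, with 11 of 14 above, Ccna2 at 192 ± 34.7 TPM and the proliferation marker Mki67 at 16.1 ± 8.46. Glycolysis was at 2.24 ± 1.31, with 10 of 13 above, Pfkp at 89.3 TPM, and Ldha, Pkm and Gapdh at 30.2, 19.6 and 17.3 TPM. The naive and quiescent list was at 1.21 ± 0.58, with 5 of 10 above, among them Tcf7 at 14.9 and Lef1 at 11.7 TPM. The activation list was at 1.16 ± 1.31, with 5 of 12 above. Il2, Cd40lg and Il2ra had 17.8, 11.8 and 8.55 TPM. Immediate early genes were at 0.20 ± 0.35, with 3 of 9 above and Junb at 58.5 TPM. Cholesterol synthesis was at -0.05 ± 1.23, with 4 of 12 above and Mvd at 10.6 TPM. The interferon response list was at -3.32, the value of a gene with 0 counts, with 2 of 14 above, Usp18 at 5.14 TPM and Irf7 at 2.67. Other genes named here share exon bases too: Ccna2 510 with Exosc9, Pfkp 372 with Pitrm1, Lef1 1208 with Gm43352 and Junb 173 with Prdx2. The same holds for Gapdh, Usp18 and Irf7, with 68, 124 and 45 bases. Counts of such genes may come in part or mainly from the gene opposite, and their TPM is then not a level of the gene named. Among the state lists, the level of replicate 4 was lower than those of the other libraries for pan-T, naive, activation, cell cycle, glycolysis and cholesterol synthesis genes.

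Lists of other cell types were near 0 counts on the strand counted. All 4 CD8 T cell, 9 dendritic cell and 8 NK cell and ILC members share no exon bases with the other strand. If counts lie on the strand opposite to the transcripts, such genes keep few counts even where expressed. Low levels therefore do not show that other cell types were absent. The median was -3.32 for B cells, plasma cells, macrophages and monocytes, neutrophils, mast cells and basophils, NK cells and ILC, erythroid cells, and stroma and epithelium. It was -3.15 ± 0.34 for CD8 T cells and -3.02 ± 0.60 for dendritic cells. The members called above 1 TPM included Csf1r, the macrophage growth factor receptor, at 148 ± 21.7 TPM, which shares 871 exon bases with Hmgxb3, and Alas2 at 10.4 ± 2.14 TPM, which shares exon bases with Apex2. The others were Cd68 at 6.29 ± 3.19, Cd79a at 5.92 ± 1.52 and Cd74 at 3.50 ± 0.909 TPM, with 6 to 18 counts of Cd68, 9 to 15 of Cd79a and 4 to 9 of Cd74 per library. Cd8b1 had 3 or 4 counts in each library. The 9 lists with a median above 1 TPM among all 27 were those of the Th2 and Treg programs, pan-T, naive, activation, cell cycle, glycolysis, immediate early and mitochondrially encoded genes.

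Across the genome, 5523 of the 17203 genes with a count were called above 1 TPM and 4571 below (limma moderated one-sample test, adjusted p under 0.05). For a gene of the median exon length of 3103 bases, 1 TPM was 3.82 to 5.15 counts, so the number below rested on few counts. Without any 1 replicate it was 2410 to 2928, and with a mean count of at least 10 it was 13.

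Genes that varied between replicates were sought with edgeR. Its default filter, with 1 group, needed counts in each of the 4 libraries, so genes near 0 in 1 library, such as Tsix, were not tested. None of the 4190 genes left passed an adjusted p under 0.05, and 268 had an unadjusted p under 0.05, where chance would give 5%. The smallest adjusted p from edgeR was 0.153. The edgeR test called 345 of 17203 genes with no filter beyond a count above 0 and 8 of 10968 with a mean CPM of at least 1. With limma-trend 1 gene passed, 15 genes were dispersion outliers in DESeq2, and without replicate 4 edgeR called 20. As no gene passed with the filter fixed in advance, none was named and no list could be tested for over-representation. In simulated counts of these libraries with 1 library changed 4-fold, the edgeR test found 118 of 198 changed genes (59.6%). The simulation gave all genes the same dispersion and changed only genes with higher counts. That share may therefore overstate what the test could find in the measured counts.

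Replicate 4 stood apart at genes that share no exon bases with the other strand. Of 1156 such genes among those tested, 304 (26.3%) were more than 1 lower on the log2 scale in replicate 4 than in the mean of the others, and 28 were more than 1 higher. For replicates 1, 2 and 3 the numbers lower were 15, 6 and 2. The filter removed genes that fell far in 1 library. Among genes with at least 10 counts in each of the other 3 libraries, a choice made after the data had been seen, 1066 of 2115 without shared exon bases (50.4%) were more than 1 lower in replicate 4, with a median of -1.02. In replicates 1, 2 and 3 the same choice gave 2.65%, 3.77% and 2.37%. Among features that share at least 50 exon bases it gave 244 of 3150 lower and 157 higher in replicate 4. Ptprc, the CD45 phosphatase of white blood cells, had 175, 273, 208 and 25 counts, and Mki67 243, 267, 341 and 52. Hspa8, a chaperone, had 297, 416, 328 and 69. Among the 2872 tested features that share at least 50 exon bases, 91 were more than 1 lower and 107 more than 1 higher in replicate 4. The latter included Gm11175, opposite the transcription factor gene Jund, with 10258, 12707, 11314 and 23490 counts, and Mfsd11, opposite Srsf2, with 5584, 6650, 6730 and 16666. These genes were chosen after their values were seen. Mettl23, which shares 460 exon bases with Srsf2 against 288 for Mfsd11, did not rise, with 12500, 12337, 12443 and 11931 counts.

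**Figure D2:**
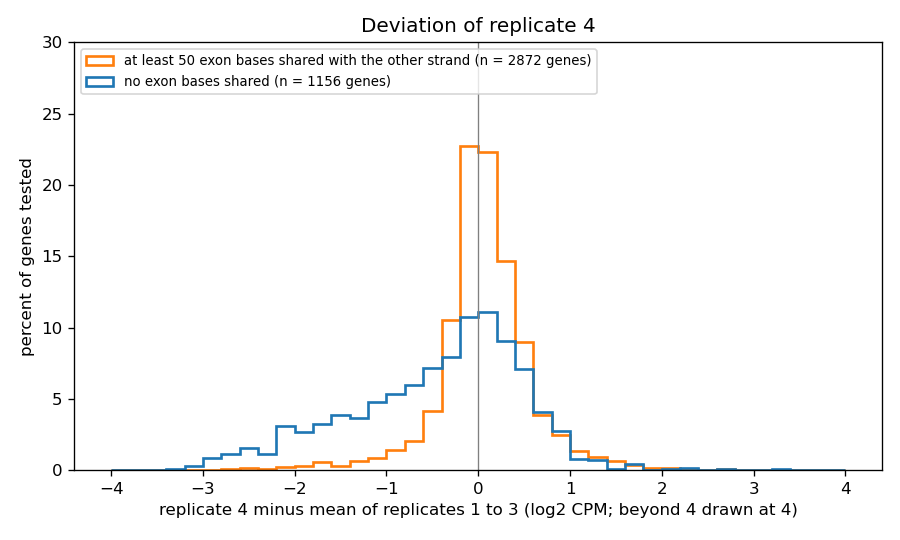
Distribution of the log2 CPM of replicate 4 minus the mean of replicates 1 to 3, as a percentage of genes tested, for 2872 genes with at least 50 exon bases shared with the other strand and 1156 with none. The median was 0.05 in the first set and -0.27 in the second, where 26.3% of genes lay below -1; genes near 0 in 1 library were not tested and are not drawn.

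Library-type lists also set replicates apart. CT010467.1, a ribosomal RNA gene on chromosome 17 (39846353 to 39848827, mm10), took 1.02% of the counts in replicate 1 (95% Wilson interval 1.01 to 1.04), 1.14% in replicate 2 (1.13 to 1.16), 28.6% in replicate 3 (28.57 to 28.68) and 14.4% in replicate 4 (14.37 to 14.47). CT010467.1 shares 1822 exon bases with Gm42418 on the other strand, which had 33, 36, 1065 and 45 counts. Ccdc107, which lies opposite the structural RNA gene Rmrp, had 16, 14, 914 and 235 counts. Replication-dependent histone genes had a median log2(TPM + 0.1) of -2.53 ± 1.59, and structural RNAs -3.32. Hist1h3c had 4.78 TPM and Rn7s1 2.96. The sex-linked list was at -2.84 ± 0.96. Tsix had 7 and 2 counts in replicates 3 and 4, and Xist 8 and 2. Eif2s3y, Ddx3y and Kdm5d on chromosome Y had 10, 9 and 7 counts in replicate 3 and 1 or 0 in each other library. Mitochondrially encoded genes were at 7.40 ± 0.98.

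**Figure D3:**
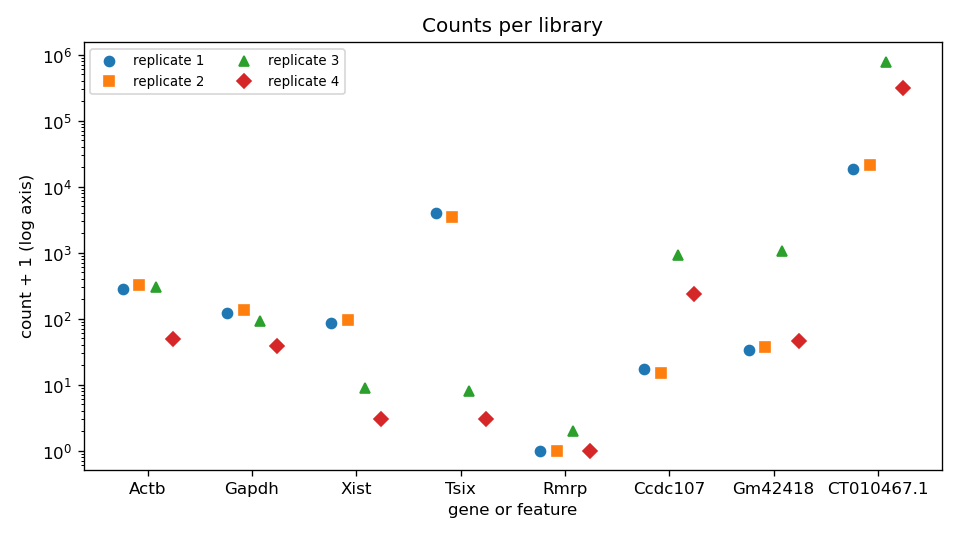
Counts plus 1, on a log axis, of 8 genes and features in replicates 1 to 4, chosen after their values were seen. Tsix had 4004 and 3437 counts in replicates 1 and 2 and 7 and 2 in replicates 3 and 4, and CT010467.1 had 18450 and 21080 in replicates 1 and 2 and 776235 and 312900 in replicates 3 and 4.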

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

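The tests with the mitochondrial genes and those of pairs of a list gene and the feature opposite were chosen only after the results were seen. Each reported value was checked for a library far from the other 3, and 27 of 153 values met that criterion. Chance gives about 1 in 20 for continuous values, but 16 of the 27 set 1 library against 3 tied values, which meet it by construction, so that rate cannot be applied to the number. Replicate 3 was the far library in 11, replicate 4 in 8, replicate 2 in 6 and replicate 1 in 2.

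In replicate 4 the list levels in median log2(TPM + 0.1) were low for the Tfh program at -3.32 and the cell cycle at 0.52. Replicate 4 was also low in Tcf7 at 5.89 TPM, Mki67 at 3.48, Runx3 at 0.269 and Cxcr5 at 0, and apart in Il13 minus Ifng at -2.63 and Il5 at 0.437 TPM. Replicate 3, the deepest library, was high in the raw count of mt-Nd6 at 49430. As a share of counts mt-Nd6 was not high there, at 2.05%, 1.94%, 1.82% and 1.66% in replicates 1 to 4. Replicate 3 was also high in the levels of replication-dependent histones at -0.13 and sex-linked genes at -1.40, and in the TPM of Eif2s3y at 1.45, Ddx3y at 1.04, Kdm5d at 0.278, Rmrp at 2.22, Ighd at 0.317, Gata2 at 0.112 and Il17a at 0.515. Il4 minus Il17a was low there at 4.33. Replicate 2 was high in the levels of CD8 T cells at -2.65 and dendritic cells at -2.13, and in the TPM of Bcl6 at 0.237, Il13 at 0.658, Crtam at 0.155 and Xcr1 at 1.602. Replicate 1 was high in Il10 at 0.620 TPM and Ccr6 at 0.400. The values of Il5, Il13, Il10, Il17a, Ccr6, Crtam, Ighd, Gata2 and Rmrp each rest on 1 count.

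Low counts of housekeeping genes stood beside high counts of features opposite expressed genes. Where Tsix and Xist reached 50 counts, Tsix exceeded Xist by at least 36.6-fold, which is consistent with counting on the strand opposite to the transcripts of a stranded library. The prediction for ribosomal protein genes was not met in either direction: 56.25% of 16 had fewer counts than the gene opposite in all libraries, with shared stretches as short as 14 bases. An unstranded library is argued against by mt-Nd6, at least 6.13 times the 12 heavy-strand genes together. The median ribosomal protein ratio, 0.136 to 0.601, met neither bound set for an unstranded library. Antisense transcription in the cells is argued against by mt-Nd6 only for the mitochondrial genome, and for nuclear genes it was not tested. The library kit is not named in the sources used here, and strand-separated tracks are the only label of it besides the header paths.

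Replicate 4 was lower at genes with no shared exon bases, but over 26 pairs of a list gene and the feature opposite, the median deviation of replicate 4 was -0.30 for the genes and 0.13 for the features, too small a fall to decide. A narrower test was then chosen, after those values were seen, of the 11 genes whose mean count was under 0.1 of the feature's: they were at -1.68 and their features at 0.19. Since that choice used the counts of replicate 4, it was repeated with replicates 1 to 3 alone, which gave 10 pairs, at -1.60 and 0.20. That argues against lower expression of those 10 genes, for which a smaller residual share of wrong-strand fragments in replicate 4 may account. The genes with no shared exon bases have no feature opposite, so for each of them both explanations stay open. As sets, among genes with at least 10 counts in each of the other 3 libraries, the medians in replicate 4 differed. They were -1.02 over 2115 genes without shared bases and 0.16 over 3150 features with at least 50. That argues against a fall in expression common to both sets. What could cause lower expression in replicate 4 was not tested, as the design has 1 group.

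Replicate 4 was higher at many features opposite another gene and lower at many others. Among those with at least 10 counts in each of the other 3 libraries, 244 of 3150 were more than 1 lower and 157 more than 1 higher in replicate 4. DESeq2 size factors and TMM centre the median themselves, so the median of 0.057 with the former decides little, and with totals, which do not, it was -0.051. A change of scaling moves each feature of a library alike and is argued against by the spread, with 91 of 2872 features below -1 and 107 above 1. Over 2859 features, the Spearman correlation of the deviation with GC content was 0.26 in replicate 4 and -0.24, -0.04 and -0.17 in replicates 1 to 3. This lies between the bounds of 0.1 and 0.3 set before, so GC content may contribute but cannot be told apart from other causes here.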

How the results depend on the processing

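Alternatives that drop CT010467.1, keep only list members with no shared exon bases or change the limit for features opposite list genes were chosen after the data had been seen. The 12 contrasts kept their direction in 79 of 83 alternatives. Their p-values could not pass 0.05 with 4 libraries, so these say nothing about significance. With members of a mean count of at least 10, Th2 minus Th1 was -1.47 and Th2 minus Tfh -0.095, on fewer genes, and Th2 minus Th17 could not be computed, as no Th17 gene passed. Il4 minus Il21 was -0.25 on CPM, which omits the gene length. Il13 minus Ifng lay between -0.88 and 0.030 with a replicate left out, positive without replicate 4, on 3 counts in all. The number of genes below 1 TPM, 4571, was 39383 with no filter, which adds genes at 0, 13 with a mean count of at least 10, 2554 and 7779 at levels of 0.5 and 2 TPM, and 2410 to 2928 with a replicate left out. The number above 1 TPM stayed within 1.5 times of 5523. Variable genes numbered 345 with no filter beyond a count above 0, 8 with a mean CPM of at least 1, 1 with limma-trend and 15 as DESeq2 dispersion outliers, against 0. With a replicate left out they numbered 0 to 20, with 20 without replicate 4; the cause was not tested. The number of lists above 1 TPM was 8 to 11. For single lists, 61 of 189 alternatives left the level unchanged, 97 moved it by less than 1 SD and 31 by more. All 61 were in lists whose median was that of a gene with 0 counts in every library. Rescaling or leaving out a replicate cannot move such a median, and its SD is 0, so any change of it counts as more than 1 SD. In 6 of the 189 alternatives the level was on the other side of 1 TPM, in the Th2, Tfh, cholesterol synthesis and immediate early lists. For features opposite list genes, the exact p was 0.0015 to 0.018 in 4 alternatives. Posterior mean TPM was not run, since the tables hold counts. Depth limits every gene at 3 counts or fewer.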

Other observations

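The data split replicates 1 and 2 from 3 and 4 at several loci. Tsix, opposite Xist, had 4004 and 3437 counts in replicates 1 and 2 and 7 and 2 in replicates 3 and 4. CT010467.1 and Ccdc107, the latter opposite Rmrp, were higher in replicates 3 and 4, as was Gm20628, opposite the histone gene Hist2h3b, with 39, 26, 253 and 146 counts. The labels record no sex and no batch, and whether the replicates differ in sex was not tested.

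A prediction written before its result was seen was that poly(A) selection would leave histone genes over 3 below the cell cycle list in each library. The mean difference was -4.90 in median log2(TPM + 0.1), but the criterion was missed in replicate 3, where the histone list was at -0.13 and the cell cycle list at 2.77. Moreover, if counts lie on the other strand both medians are not those of the transcripts, so the test decides nothing either way. Features opposite histone genes had counts: 4930558J22Rik opposite Hist1h4b had 270.2 ± 63.5 (SD, n = 4).

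Il4 had 26 counts in replicate 4, against 24, 21 and 25 in the others, and Nrp1 had 149, 150, 145 and 155. Neither shares exon bases with an annotated gene on the other strand, and neither was lower in replicate 4.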
